A study of Homo sapiens with 181 samples.

How the data were processed

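The series measured RNA with the GeoMx Human Whole Transcriptome Atlas, a set of barcoded probes that is read by sequencing, on one tissue microarray of fixed high-grade serous ovarian cancer tissue. Per the labels, the array held 55 cores of 2 mm from 30 patients, taken from tumours of the ovary, omental metastases and adjacent stroma without tumour. A pathologist chose the regions by staining for pan-cytokeratin, CD45 and CD163 with a nuclear stain, kept away from necrosis and big vessels, and each region was divided into areas of at least 50 cells by the same stains. The 4 area types are cancer (positive for pan-cytokeratin), CD163 (monocytes and macrophages), CD45 (positive for CD45 and negative for CD163) and stroma (negative for all 3 antibodies). Because keratins, PTPRC (the gene of CD45) and CD163 chose the areas, their own differences are no finding here. Counts and camera values of the epithelial list are given without its 4 keratins, a choice made after the data were seen; the number of calls over all lists, 89 with 55 that hold, is the same either way.

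The deposited table holds a signal per target and area, for 18677 targets. Every area had been multiplied by one factor that sets its negative probes (probes with no human target) to the same value, 6.729, with a largest difference of 1.78e-15 between areas, while the third quartiles of the areas were left to differ. No further scaling was found in the values. The genome build is GRCh 38.p13 per the submitters' processing notes, and the read processing software is not given in the sources used here. The 2 wells without template have no column in this table. Of the targets, 18365 matched a symbol in the RefSeq gene table of GRCh38.p14, which was used for names alone, so no coordinates are given.

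Whole reads could be recovered from the deposited signal: 100% of values were whole multiples of the value of 1 read within a tolerance of 0.01. The lowest value in any area was 1 read and 0 values were zero; how genes without reads were treated before deposit is not given in the sources used here. Recovered totals ran from 18789 to 4028199 reads per area, with medians of 1021218 in cancer, 390142 in stroma, 71740 in CD163 and 35354 in CD45 areas. An area with over 50% of its genes at 1 read is called shallow here, which was chosen after the data were seen; 34 areas were shallow. In a shallow area most genes lie at the lowest value of that area, which limits the precision of low genes and can shift their values. The negative probes, which set the scale, had a median of 1.23 recovered reads in CD45 and 2.16 in CD163 areas, with a lowest of 1. In stroma and cancer areas the medians were 11.8 and 23.7. The scale of many CD45 and CD163 areas thus rests on negative probes near the 1-read floor.

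After the negative probe and 23 XIST and Y-linked targets were left out, 18653 genes remained. The 9633 genes with a value over 2 times the negative probe in at least 10% of areas were tested. The main test was limma (version 3.58.1, R 4.3.3) with a trend in the variance on log2(value + 1), with area type and region number as fixed terms, over the areas of all 4 types, 2-sided, with Benjamini-Hochberg adjustment over the genes of each of the 6 comparisons and a threshold of 0.05. Differences on the log2(value + 1) scale understate the change of low genes, the more so in shallow areas. They and their p-values come from this one fit, while the regions counted beside a comparison are those that hold both area types. The region number is given in each sample's label, so areas with one number come from the same piece of tissue. Deviations from the type means were checked: their correlation had a median of 0.193 over 209 pairs of areas from one region and -0.004 over 11704 pairs from different regions. Patients are not tied to regions in the labels. With 65 regions from 30 patients some regions share a patient, so p-values over regions are too small in every test reported.

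Gene lists (28, of cell type markers and pathways) were fixed before the data were examined, as were the tests, most alternatives and the rule for named genes. Some lists share genes: C1QA, C1QB and C1QC are macrophage markers and complement components, and VSIG4 is a macrophage marker and a complement regulator. The calls of these lists are therefore not independent. Lists with at least 3 genes tested (26) entered camera with a preset correlation between genes of 0.01, adjusted by Benjamini-Hochberg over 156 lists and comparisons, and again with the correlation estimated from the data. Camera sets a list against all other genes tested, so its up and down are relative to them. The rule names, per comparison, up to 10 genes with the largest difference in each direction among those past the threshold, with the same direction in at least 80% of regions holding both area types and a mean in the higher type of at least 4 times the negative probe. It adds NNMT, up to 4 members with the smallest adjusted p of each list that camera called, and the complement components. Other named genes are said to be chosen after their values were seen. Immunoglobulin, HLA, T cell receptor constant and C4 genes have near-identical copies, so their values are uncertain between copies.

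Relations between NNMT in stroma and list scores (mean over members of centred log2 values) used Pearson's r and Spearman's rho with 2-sided permutation tests of 100000 resamples, adjusted over 19 relations. Scores were also set among 10000 random lists of the same size matched on mean level, and mclust (version 6.1.1) was used to look for clusters of NNMT over regions; both checks, and the relations of single complement genes, were added after the data were seen. Stroma of regions with and without a cancer area was compared with limma and a plate term.

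The alternatives chosen then were no region block, region as a random block, a pseudocount of 5, no filter, a filter at 50% of areas (2113 genes), quantile normalization, subtraction of the negative probe with scaling to the third quartile, regions with all 4 area types, each of the 2 collection plates, and edgeR's quasi-likelihood test (version 4.0.16) on recovered reads with TMM or RLE scaling. Scaling to the third quartile, leaving out shallow areas, both together, edgeR without shallow areas and a covariate of recovered negative-probe reads were added after the data were seen. The planned covariate of the negative-probe value was not run, because that value is the same in every area. The limma step was tested on simulated data: for 9633 genes with 200 changed, it recovered 83.6% of 1.5-fold and 100% of 2-fold changes between stroma and cancer, 70.1% and 100% between CD163 and CD45, 74.6% and 98.5% between CD163 and stroma, 50.7% and 97% between CD45 and stroma, 53.7% and 100% between CD163 and cancer, and 49.3% and 95.5% between CD45 and cancer areas. For stroma of regions with against without a cancer area it recovered 49.3% and 97%. Every gene was simulated with a dispersion of 0.0488 and a log2 SD of 0.3 between regions. The spread of single genes was not copied, so recovery in the real data may be lower. Unchanged genes made up 0.526%, 30.5%, 7.61%, 13.2%, 7.65% and 21.3% of the simulated calls of the 6 comparisons in the same order. They made up 0.606% for stroma with against without a cancer area. Without shallow areas the 6 shares were 0.521%, 28.1%, 15.4%, 25.4%, 21% and 33.3%, so leaving those areas out raised most of them. Simulated calls that involve CD163 or CD45 areas thus held more false ones than the threshold of 0.05 sets. The shares depend on how many genes were changed, so they are no estimates for the real calls, which may hold more false ones as well. Columns left without a sample numbered 0. The single-gene results of 2 genes are not reported here, though their lists were tested whole.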

Results

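RNA levels were measured in areas of 65 regions on a tissue microarray of high-grade serous ovarian cancer: 55 stroma, 46 cancer, 43 CD163 and 35 CD45 areas. All 4 types were collected in 27 regions. The series concerns NNMT, the enzyme that transfers a methyl group from S-adenosylmethionine to nicotinamide, in cancer-associated fibroblasts, and the comparisons between areas of the same region ask which compartment holds NNMT and the genes around it. Depth differed by type. The median area held 1021218 recovered reads in cancer, 390142 in stroma, 71740 in CD163 and 35354 in CD45 areas. Over 50% of genes lay at 1 read in 20 of the 35 CD45 areas (57.1%) and in 12 of the 43 CD163 areas (27.9%), against 1 stroma and 1 cancer area. In those shallow areas most genes sat at the lowest value of the area, so small differences of low genes were not detectable there. Leaving the shallow areas out also moved the median of all genes between CD45 areas and stroma from −0.131 to 0.105. With third-quartile scaling it moved from −0.018 to −0.182.

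**Figure D1:**
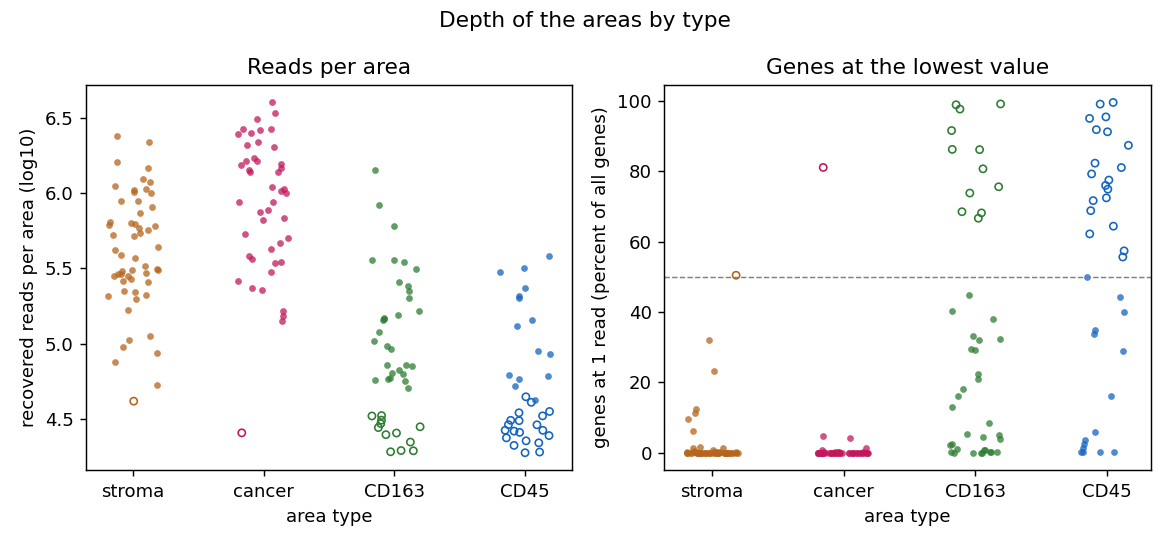
Each point is 1 area, by area type; the left panel gives recovered reads on a log10 scale, the right panel the percent of all genes at 1 read, with a dashed line at 50. Open circles are the 34 shallow areas, 20 of them CD45 and 12 of them CD163 areas.

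NNMT was highest in stroma. Its mean log2 level was 4.83 ± 1.21 in stroma (SD, n = 55), 4.40 ± 1.09 in cancer (n = 46), 4.19 ± 1.06 in CD163 (n = 43) and 4.00 ± 1.02 in CD45 areas (n = 35), against 2.95 for the negative probe. It exceeded 2 times the negative probe in 70.9% of stroma, 58.7% of cancer, 55.8% of CD163 and 48.6% of CD45 areas. Within regions, NNMT was higher in stroma than in cancer areas by 0.57 ± 0.14 (log2 difference ± SE, limma, Benjamini-Hochberg adjusted p = 2.97e-04, 26 of 38 regions). It was lower than in stroma by −0.92 ± 0.14 in CD163 areas (limma, adjusted p = 1.59e-08, 34 of 42 regions) and by −1.19 ± 0.15 in CD45 areas (limma, adjusted p = 1.26e-11, 29 of 33 regions). CD163 and CD45 areas did not differ past the threshold (0.27 ± 0.15, limma, adjusted p = 0.317). Within plate 1 the 3 differences were 0.42, −0.49 and −0.78, and within plate 2 they were 0.70, −1.42 and −1.67; the CD163 difference in plate 1 missed the threshold (limma, adjusted p = 0.0676). Without the region block the difference between stroma and cancer was 0.43 and missed it too (limma, adjusted p = 0.0759). NNMT was also lower in CD163 and CD45 than in cancer areas, by −0.35 ± 0.15 (limma, adjusted p = 0.0263) and −0.62 ± 0.16 (limma, adjusted p = 3.11e-04). Set against the median of all genes these were 0.03 and −0.18, and with third-quartile scaling both calls ended (−0.01 and −0.18). Both also ended without shallow areas (−0.12 and −0.20), where the differences from stroma shrank to −0.67 in CD163 and −0.74 in CD45 areas. Mean levels were then 4.84 in stroma, 4.44 in cancer, 4.58 in CD163 and 4.60 in CD45 areas (n = 54, 45, 31 and 15). The order of the means of cancer and immune areas thus turned. Regions share patients, so these p-values are too small.

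**Figure D2:**
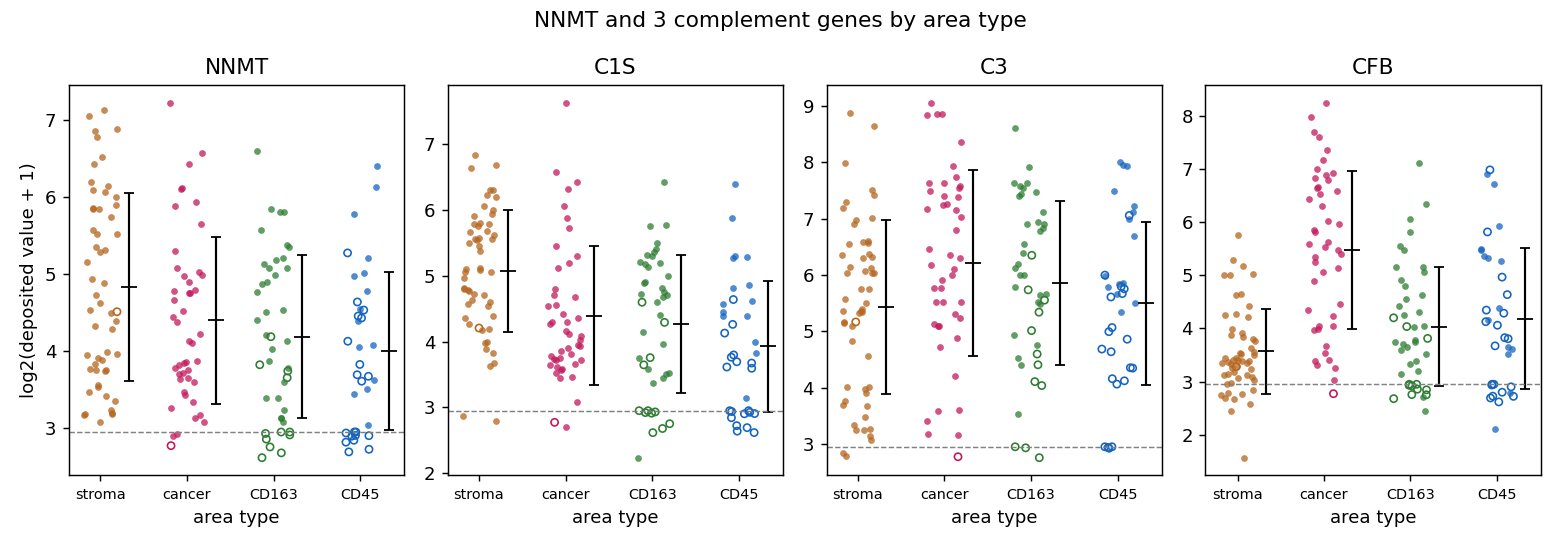
Each point is 1 area on the log2(deposited value + 1) scale, by area type, for NNMT and the complement genes C1S, C3 and CFB; open circles are shallow areas, black bars the mean ± SD, and the dashed line the negative probe (2.95). NNMT and C1S had their highest means in stroma, while CFB had its highest mean in cancer areas; the direction of C3 between stroma and cancer turned to 0.05 with quantile normalization.

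Stroma was higher than cancer areas in matrix genes (38 regions hold both). COL1A1 and COL1A2, the chains of type I collagen, were higher in stroma by 3.42 ± 0.20 and 3.08 ± 0.20, and COL3A1 by 2.65 ± 0.16. The matrix glycoprotein SPARC was higher by 2.09 ± 0.14 and the proteoglycan BGN by 2.13 ± 0.16. AEBP1, a matrix-associated repressor, was higher by 2.30 ± 0.14, and COL6A2 of type VI collagen by 2.25 ± 0.16. Each of these 7 genes was higher in at least 37 of 38 regions (limma, largest adjusted p = 2.42e-30). All 21 fibroblast and matrix markers tested were higher in stroma, with a median 2.04 above that of all genes. All 14 TGF-beta and matrix remodelling genes were higher too, among them the matricellular factor CCN2 by 1.14 ± 0.15, the activin subunit INHBA by 0.97 ± 0.12 and COL11A1 by 0.99 ± 0.12. Contractile genes rose in 7 of 8, with ACTA2 (smooth muscle actin) at 1.35 ± 0.13, CALD1 at 1.34 ± 0.14 and TAGLN at 1.10 ± 0.16. Endothelial markers rose in 5 of 7, with ENG at 1.23 ± 0.13 and PECAM1 at 0.82 ± 0.13.

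Immune and secreted genes were also part of the stroma signal. Macrophage markers were higher in stroma in 12 of 18 and lower in 0. Plasma cell markers were higher in 6 and lower in 2 of 11, with the immunoglobulin gene IGKC at 2.36 ± 0.23. T cell markers were higher in 2 (TRBC1 at 0.45 ± 0.13 and IL7R at 0.33 ± 0.12) and lower in 1 of 11. Inflammatory fibroblast cytokines were higher in 2 of 7, the chemokines CXCL14 (0.66 ± 0.12) and CCL2 (0.56 ± 0.13). Complement components split: 6 of 13 were higher and 4 lower in stroma. C7, a part of the membrane attack complex, was higher by 1.37 ± 0.15 and the C1 protease C1S by 0.57 ± 0.14. C1QA, C1QB and C1QC, the recognition subunits of C1, were higher by 0.80 ± 0.15, 0.78 ± 0.16 and 0.89 ± 0.15. CFB, the protease of the alternative pathway, was lower by −1.79 ± 0.14, and C2, C3 and C6 by −0.57 ± 0.13, −0.56 ± 0.18 and −0.27 ± 0.11. C2 and C3 were no longer called with third-quartile scaling (−0.24 and −0.21), where C6 turned to 0.06, and C3 turned to 0.05 with quantile normalization. C1R (0.27 ± 0.13) was not called. C1S was not called within plate 2 (0.29, against 0.79 within plate 1).

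Cancer areas held the epithelial genes. All 16 epithelial tumour markers other than keratins, which chose the areas and are left out of the counts here, were lower in stroma, with a median −1.37 from that of all genes. WFDC2, the secreted protein HE4, was lower by −2.83 ± 0.16, the protease inhibitor SLPI by −2.53 ± 0.15, the mucin MUC1 by −2.27 ± 0.14 and mesothelin (MSLN) by −2.19 ± 0.13. Outside the lists, the laminin receptor BCAM was lower by −2.45 ± 0.15, the sodium channel subunit SCNN1A by −2.10 ± 0.13 and the laminin chain LAMA5 by −1.97 ± 0.12. Of the hypoxia and glycolysis genes 8 of 10 were lower, among them the glucose transporter SLC2A1 (−1.08 ± 0.13), the glycolytic enzymes TPI1 (−1.28 ± 0.16) and ENO1 (−1.15 ± 0.14), and VEGFA (−0.93 ± 0.13). All 10 proliferation genes were lower, such as BIRC5 (−0.87 ± 0.12), UBE2C (−0.80 ± 0.12) and MKI67 (−0.72 ± 0.11). Of 15 nicotinamide and methionine cycle genes, NNMT alone was higher in stroma and 11 were lower, with no camera call (adjusted p = 0.14). Complement regulators and receptors were lower in 4 of 10 with no camera call (adjusted p = 0.743). With third-quartile scaling 6 proliferation genes and 5 of the nicotinamide list were lower, and of the regulators 3 were higher and 2 lower.

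Between stroma and cancer areas limma called 358 genes higher and 5675 lower in stroma, 58 and 260 of them by at least 2-fold. The median of all 9633 genes was −0.30, which is the shift the values below are set against. The split was 1268 to 1406 with third-quartile scaling, 1115 to 2309 with quantile normalization and 1149 to 1468 with the negative probe subtracted. By edgeR on recovered reads it was 2854 to 2447 or 2282 to 2871 with TMM or RLE. Against that shift NNMT stood at 0.87, COL1A1 at 3.73, CFB at −1.49, C3 at −0.26 and MKI67 at −0.42. Camera called the fibroblast (adjusted p = 1.65e-87), TGF-beta (2.41e-28), contractile (1.35e-14), endothelial (4.88e-09), macrophage (1.35e-14), plasma cell (1.63e-11), T cell (2.3e-04), complement (1.79e-06) and cytokine (0.00126) lists up and the epithelial list (6.82e-32) down, and these hold with an estimated correlation. Proliferation and hypoxia were called down (adjusted p = 0.00333 and 0.00497), but were lost, at adjusted p = 0.122 and 0.222 with an estimated correlation. Cytotoxic, MHC class II, lysosome and ovarian stroma lists were called up against the shift (adjusted p = 0.0397, 0.0294, 0.0141 and 0.0098) and lost, at adjusted p = 0.264, 0.469, 0.324 and 0.0799 with an estimated correlation. Adjusted over the list alone, the counts higher and lower were the same for the fibroblast, TGF-beta, epithelial, endothelial, plasma cell, cytokine, nicotinamide and proliferation lists. They were 8 and 0 for contractile genes, 13 and 0 for macrophage markers, 2 and 0 for T cell markers, 7 and 4 for complement and 0 and 9 for hypoxia. These p-values are too small, since regions share patients.

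CD163 areas, set against stroma (42 regions hold both), carried a macrophage profile and were lower in the matrix genes. The C1q genes C1QB, C1QA and C1QC were higher in CD163 areas by 2.11 ± 0.16, 2.06 ± 0.15 and 1.84 ± 0.15. The lysosomal thiol reductase IFI30 was higher by 1.77 ± 0.16 and the lysosomal membrane protein LAPTM5 by 1.71 ± 0.16. Osteopontin (SPP1) was higher by 1.69 ± 0.15, the lipid carrier APOE by 1.59 ± 0.15 and RNASE1 by 1.56 ± 0.16 (limma, largest adjusted p = 5.83e-18). All 18 macrophage markers and all 10 MHC class II genes were higher, the invariant chain CD74 by 1.80 ± 0.19 and HLA-DRA by 1.42 ± 0.16. Lysosome and phagocytosis genes rose in 8 of 12, with the cathepsins CTSB (1.40 ± 0.16), CTSZ (1.17 ± 0.14) and CTSL (0.88 ± 0.12), and complement regulators and receptors in 4 of 10, with VSIG4 (0.94 ± 0.12) and ITGAM (0.54 ± 0.11). Neutrophil and myeloid suppressor markers rose in 2 of 4, the scavenger receptor OLR1 (0.56 ± 0.11) and S100A9 (0.46 ± 0.11), and checkpoint genes in 2 of 5, with HAVCR2 at 0.51 ± 0.12.

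The same CD163 areas were lower than stroma in all 21 fibroblast and matrix markers, with COL1A1 at −1.93 ± 0.20, COL1A2 at −1.85 ± 0.19 and BGN at −1.53 ± 0.15 (42 of 42 regions), and AEBP1 at −1.61 ± 0.14. CCN1, a matricellular protein, was lower by −1.57 ± 0.14. All 8 contractile genes fell, with CALD1 at −1.38 ± 0.13, TAGLN at −1.19 ± 0.15 and ACTA2 at −1.11 ± 0.13. TGF-beta genes fell in 11 and rose in 1 of 14, with CCN2 at −1.35 ± 0.14 and INHBA at −0.78 ± 0.11. Vascular genes were lower in 2 of 7 endothelial markers (VWF at −0.68 ± 0.11) and 2 of 4 pericyte markers (MCAM at −0.52 ± 0.11), and plasma cell genes in 7 of 11 (IGHA1 at −0.93 ± 0.18). Complement components went both ways, 4 higher and 5 lower of 13. Beside the C1q genes C2 was higher (0.42 ± 0.12), and among others C1S (−0.79 ± 0.13), C7 (−0.77 ± 0.15), C4B (−0.66 ± 0.16) and C1R (−0.53 ± 0.13) were lower. C4B was no longer called without shallow areas (−0.32), while C3 (−0.05 ± 0.17) and CFB (0.26 ± 0.14) were not called. Epithelial markers other than keratins were higher in 2 of 16, SLPI by 0.65 ± 0.15 and WFDC2 by 0.62 ± 0.16. Of the nicotinamide list NAMPT, the enzyme that makes nicotinamide mononucleotide, was higher (0.49), and NNMT and SHMT1 (−0.39) were lower, with no camera call (adjusted p = 0.699); NAMPT and SHMT1 were chosen after their values were seen.

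Between CD163 areas and stroma limma called 276 genes higher and 682 lower, 28 and 35 by at least 2-fold. The split turned to 691 to 361 without shallow areas, but was 335 to 1894 without them with third-quartile scaling; it turned to 447 to 231 within plate 1, against 41 to 732 within plate 2. It was 383 to 1717 with quantile normalization, 544 to 480 with the negative probe subtracted and 978 to 697 or 980 to 668 by edgeR with TMM or RLE. Without the region block 225 and 1263 genes were called. Camera calls that hold with an estimated correlation were macrophage (adjusted p = 2.14e-84), MHC class II (5.15e-33), lysosome (2.68e-21), complement regulators (6.98e-05) and neutrophil (3.01e-04) up, and fibroblast (2.48e-56), contractile (6.33e-21), TGF-beta (4.43e-10) and pericyte (0.00695) down. Complement components (adjusted p = 3.66e-04), epithelial (5.87e-05), checkpoint (0.0172) and MHC class I (0.00102) were called up and plasma cell (1.26e-05) and endothelial (0.00695) down, and lost, at adjusted p = 0.104, 0.101, 0.0923, 0.206, 0.0924 and 0.0555 with an estimated correlation. Adjusted over the list alone the counts were 9 higher for lysosome genes, 5 and 5 for complement, 0 and 3 for endothelial and pericyte markers and the same for the other lists counted here. Because regions share patients, these p-values are too small.

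CD45 areas, set against stroma (33 regions hold both), carried T cell and cytotoxic genes. The T cell receptor genes CD3E, TRAC and TRBC1 were higher by 0.96 ± 0.12, 0.91 ± 0.12 and 0.79 ± 0.14 and the adhesion receptor CD2 by 0.62 ± 0.12; 9 of 11 T cell markers rose. Cytotoxic genes rose in 6 of 7, with the chemokine CCL5 at 0.96 ± 0.13, the granule genes NKG7 at 0.65 ± 0.13 and GZMA at 0.60 ± 0.13, and CST7 at 0.50 ± 0.12. Without shallow areas (15 regions) these were larger: CCL5 1.54, TRBC1 1.48, NKG7 1.43, TRAC 1.25, GZMA 1.17 and CD3E 1.16. The median of all genes rose as well, from −0.131 in all areas to 0.105, and these values are not set against that shift. Within plate 2 TRBC1, CD2, CCL5, NKG7, GZMA and CST7 were not called (GZMA at 0.02, against 1.01 within plate 1). Epithelial markers other than keratins rose in 5 of 16, with SLPI at 0.85 ± 0.16, WFDC2 at 0.48 ± 0.17 and CLDN4 at 0.43 ± 0.13; within plate 2 SLPI and CLDN4 were not called (0.56 and 0.21) and WFDC2 turned to −0.15.

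Against stroma, the CD45 areas were lower in all 21 fibroblast and matrix markers, with COL1A1 at −2.89 ± 0.21, COL1A2 at −2.82 ± 0.21, BGN at −2.12 ± 0.17 and fibronectin (FN1) at −2.06 ± 0.17 (limma, largest adjusted p = 9.06e-26). TGF-beta genes fell in 13 of 14, with CCN2 at −1.77 ± 0.16, the membrane protease MMP14 at −1.61 ± 0.14 and CTHRC1 at −1.13 ± 0.14, and CCN1 by −2.08 ± 0.15. Contractile genes fell in 7 of 8 (TPM2 at −1.69 ± 0.15, CALD1 at −1.59 ± 0.15), endothelial markers in 5 of 7 (ENG at −1.13 ± 0.13) and pericyte markers in 3 of 4 (MCAM at −0.64 ± 0.12). Complement components fell in 8 of 13 and rose in 0, among them C1S (−1.12 ± 0.15), C1QB (−1.02 ± 0.17), C7 (−0.91 ± 0.16), C1QC (−0.81 ± 0.16), C4B (−0.77 ± 0.17), C1QA (−0.76 ± 0.16) and C1R (−0.65 ± 0.14). Macrophage markers fell in 10 of 18 (MRC1 at −0.63 ± 0.12), lysosome genes in 7 of 12 (CTSZ at −0.75 ± 0.16) and inflammatory fibroblast cytokines in 6 of 7 (CXCL14 at −0.64 ± 0.13, CCL2 at −0.53 ± 0.14). The calls of C7, C1QA, C4B, CXCL14, CCL2, MRC1 and CTSZ ended without shallow areas, at −0.56, −0.27, −0.38, −0.29, −0.13, −0.40 and −0.33. These values are not set against the median of all genes, which was 0.105 there and −0.131 in all areas.

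Between CD45 areas and stroma limma called 114 genes higher and 1602 lower, 0 and 79 by at least 2-fold, with a median of all genes of −0.13; against that shift NNMT stood at −1.06, COL1A1 at −2.76 and CD3E at 1.09. The split turned to 850 to 261 without shallow areas, but was 165 to 1558 without them with third-quartile scaling. It was 221 to 747 with third-quartile scaling, 798 to 662 with the negative probe subtracted and 828 to 522 or 977 to 462 by edgeR with TMM or RLE, and without the region block it was 91 to 2926. Calls that hold with an estimated correlation were T cell (camera, adjusted p = 8.99e-20), cytotoxic (9.14e-15) and epithelial (1.16e-08) up, and fibroblast (2.14e-84), TGF-beta (1.83e-23), contractile (2.04e-19), complement (5.44e-06), endothelial (3.22e-04), pericyte (0.0186) and cytokine (0.0074) down; without the region block the complement, pericyte and cytokine calls ended (adjusted p = 0.164, 0.111 and 0.285). Macrophage and lysosome lists were called down (adjusted p = 1.55e-04 and 0.00428) and MHC class I up (0.0473), and lost, at adjusted p = 0.264, 0.251 and 0.464 with an estimated correlation. Adjusted over the list alone, 10 T cell markers and 6 epithelial markers were higher, 14 macrophage, 9 lysosome, 8 contractile and 6 endothelial genes were lower, complement had 1 higher and 10 lower, and the other counts were the same. Regions share patients, so these p-values are too small.

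The CD163 and CD45 areas (33 regions hold both) parted into a macrophage and a lymphocyte profile. C1QB, C1QA and C1QC were higher in CD163 areas by 3.13 ± 0.17, 2.83 ± 0.16 and 2.64 ± 0.16. RNASE1 was higher by 2.65 ± 0.17, APOE by 2.35 ± 0.17, SPP1 by 2.07 ± 0.17 and the apolipoprotein APOC1 by 2.05 ± 0.16 (limma, largest adjusted p = 2.15e-25). All 18 macrophage markers were higher, as were all 12 lysosome and phagocytosis genes, with CTSB at 2.20 ± 0.18, CTSZ at 1.92 ± 0.16, CTSD at 1.68 ± 0.18 and GPNMB at 1.46 ± 0.15, and IFI30 at 2.12 ± 0.17. MHC class II genes rose in 9 of 10, with CD74 at 1.91 ± 0.21, HLA-DPA1 at 1.88 ± 0.18 and HLA-DRA at 1.59 ± 0.17. Complement components rose in 5 of 13, the C1q genes with C2 (0.51 ± 0.13) and CFD (0.49 ± 0.12), and regulators and receptors in 6 of 10, with VSIG4 (1.20 ± 0.13), the anaphylatoxin receptor C5AR1 (0.87 ± 0.15) and the C1 inhibitor SERPING1 (0.86 ± 0.16). C2 lost its call with third-quartile scaling (0.41) and C2 and CFD lost it without shallow areas (0.57 and 0.46). Matrix genes were higher too, fibroblast markers in 12 of 21 (FN1 at 1.41 ± 0.17) and TGF-beta genes in 4 of 14 (TGFBI at 1.23 ± 0.13, MMP14 at 1.15 ± 0.14), and hypoxia and glycolysis genes in 6 of 10 (VEGFA at 0.59 ± 0.13). NAMPT was the only nicotinamide list member called, at 0.81, chosen after its value was seen.

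CD45 areas were higher in T cell markers, 9 of 11, with CD3E lower in CD163 areas by −1.02 ± 0.12, TRAC by −0.88 ± 0.12 and CD2 by −0.70 ± 0.12. The same held for all 7 cytotoxic genes, with CCL5 at −0.94 ± 0.13, NKG7 at −0.58 ± 0.13 and GZMA at −0.54 ± 0.13. The direction of GZMA turned within plate 2 (0.09), and TRBC1, TRAC, CD2, CCL5 and NKG7 were not called there. Plasma cell markers were lower in CD163 areas in 2 of 11, MZB1 (−0.66 ± 0.14) and IGHA1 (−0.78 ± 0.20). In all, limma called 633 genes higher and 98 lower in CD163 areas, 58 and 2 by at least 2-fold. The split was 380 to 199 with third-quartile scaling, 317 to 184 with the negative probe subtracted, 458 to 438 or 413 to 525 by edgeR with TMM or RLE, and it turned to 288 to 461 without shallow areas, against 446 to 177 without them with third-quartile scaling and 336 to 228 by edgeR with TMM. In simulated data with 200 changed genes 30.5% of the calls in this comparison were of unchanged genes, against the 5% that the threshold sets. That share depends on the number changed and is no estimate for the real calls. Without the region block the split was 398 to 48, and within plates 987 to 95 and 83 to 10. Calls that hold with an estimated correlation were macrophage (camera, adjusted p = 1.31e-109), lysosome (9.15e-34), MHC class II (6.38e-33), complement components (1.12e-15), complement regulators (6.19e-08) and TGF-beta (6.89e-06) up and T cell (2.03e-22) and cytotoxic (1.72e-14) down. The complement components share the C1q genes, and the regulators VSIG4, with the macrophage list. Camera was not run without these shared genes, so the complement calls cannot be told apart from the macrophage call. Fibroblast (adjusted p = 5.02e-09) and hypoxia (0.00695) were called up and plasma cell (2.27e-06) down, and lost, at adjusted p = 0.0506, 0.246 and 0.0689 with an estimated correlation. Adjusted over the list alone, 10 MHC class II genes, 14 fibroblast markers, 7 complement components, 7 complement regulators, 7 TGF-beta and 7 hypoxia genes were higher, 10 T cell and 3 plasma cell markers lower, and the other counts were the same. These p-values are too small, since regions share patients.

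Against cancer areas, both immune area types were lower in all 16 epithelial tumour markers other than keratins. In CD163 areas (36 regions) WFDC2 was lower by −2.21 ± 0.17, BCAM by −2.26 ± 0.16, MUC1 by −2.04 ± 0.15, MSLN by −1.96 ± 0.13, and LAMA5 by −1.87 ± 0.12. The lysosomal gene LAPTM4B was lower there by −2.01 ± 0.16 and clusterin (CLU) by −1.75 ± 0.16. In CD45 areas (27 regions) WFDC2 was lower by −2.35 ± 0.18, LAPTM4B by −2.14 ± 0.17, BCAM by −2.13 ± 0.17, the transcription factor SOX17 by −1.99 ± 0.15 and the growth factor MDK by −1.88 ± 0.17. The CD163 areas were higher in all 18 macrophage markers (C1QB 2.88 ± 0.17, C1QA 2.87 ± 0.16, C1QC 2.73 ± 0.16, FCGR3A 1.90 ± 0.15), in LAPTM5 (2.43 ± 0.16) and IFI30 (2.07 ± 0.17). They were higher in 8 of 10 MHC class II genes (HLA-DPA1 1.83 ± 0.18) and in 9 of 12 lysosome genes (GPNMB 1.41 ± 0.14) with 2 lower. Fibroblast markers were higher in 15 of 21 and lower in 1, and TGF-beta genes were higher in 6 of 14 (TGFBI 1.24 ± 0.13). Of the complement components 6 were higher, with C7 (0.60 ± 0.16) and CFD (0.32 ± 0.12) beside the C1q genes, and 4 were lower, among them CFB (−1.53 ± 0.14) and C3 (−0.61 ± 0.18). The call of C3 ended with third-quartile scaling (−0.24) and its direction turned with the negative probe subtracted (0.03) and with recovered negative-probe reads as a covariate (0.17). The CD45 areas were higher in 9 of 11 T cell markers (TRBC1 1.24 ± 0.14, CD3E 1.10 ± 0.13, TRAC 1.04 ± 0.13) and in 6 of 7 cytotoxic genes (CCL5 1.16 ± 0.14, NKG7 0.67 ± 0.13). Plasma cell markers were higher in 6 of 11 (IGKC 1.86 ± 0.25, MZB1 0.77 ± 0.15) and lower in 2. Complement components were higher in 1 (C7 at 0.46 ± 0.17) and lower in 7 of 13, with CFB at −1.46 ± 0.16, C3 at −1.01 ± 0.20, C2 at −0.66 ± 0.14 and C1S at −0.55 ± 0.16 (no camera call, adjusted p = 0.133); with third-quartile scaling 4 were higher and 2 lower. The calls of C2 and C1S ended with third-quartile scaling (−0.22 and −0.11), that of C3 without shallow areas (−0.45), and C1S turned to 0.07 by edgeR without shallow areas. All 15 nicotinamide and methionine cycle genes were lower in CD45 areas, with AHCY, which hydrolyses S-adenosylhomocysteine, at −1.38 ± 0.14, MAT2A, which makes S-adenosylmethionine, at −1.20 ± 0.15, QPRT at −0.87 ± 0.13 and MTAP at −0.85 ± 0.13 (camera, adjusted p = 0.0258). That call was lost, at adjusted p = 0.221 with an estimated correlation, and with third-quartile scaling 4 of the 15 were lower.

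For CD163 against cancer limma called 333 genes higher and 6773 lower, 54 and 328 by at least 2-fold, and for CD45 against cancer 123 and 7307, 10 and 632 by at least 2-fold. The medians of all genes were −0.37 and −0.44, and against these C3 stood at −0.23 and −0.56, CFB at −1.15 and −1.02, and AHCY in CD45 areas at −0.94. The splits were 981 to 1697 and 886 to 1523 with third-quartile scaling, 738 to 3632 and 464 to 3736 with quantile normalization, and 1380 to 1337 and 1396 to 1166 with the negative probe subtracted. They were 2350 to 1925 and 1972 to 1290 or 1898 to 2300 and 1736 to 1395 by edgeR with TMM or RLE. For CD163, camera called macrophage (adjusted p = 3.13e-89), fibroblast (2.4e-25), MHC class II (1.09e-24), lysosome (7.37e-19), TGF-beta (3.97e-12), complement (4.18e-12), endothelial (6.98e-05), neutrophil (1.67e-04), T cell (2.76e-04) and checkpoint genes (0.00174) up and epithelial markers (4.52e-22) down, which hold with an estimated correlation. It also called plasma cell, MHC class I, interferon, cytotoxic, cytokine and complement regulator lists up and proliferation down, which were lost, at adjusted p = 0.139, 0.331, 0.152, 0.178, 0.0789, 0.104 and 0.304 with an estimated correlation. For CD45, T cell (3.7e-28), cytotoxic (1.41e-16), plasma cell (1.72e-14), fibroblast (1.63e-11), endothelial (7.06e-04) and neutrophil (0.0111) lists were called up and epithelial markers (1.97e-19) down and hold. Macrophage, TGF-beta, checkpoint, ovarian stroma, MHC class II and interferon up, and proliferation and hypoxia down, were lost, at adjusted p = 0.123, 0.0579, 0.0799, 0.141, 0.482, 0.264, 0.22 and 0.115 with an estimated correlation. Up is relative to the other genes here, whose medians lay below 0, so genes of such a list need not be higher than in cancer areas. Complement components of CD45 areas, more of them lower than higher, had the direction up by camera without a call. Adjusted over the list alone, 5 TGF-beta genes were higher in CD163 areas and the other counts given were the same. Because regions share patients, these p-values are too small.

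**Figure D3:**
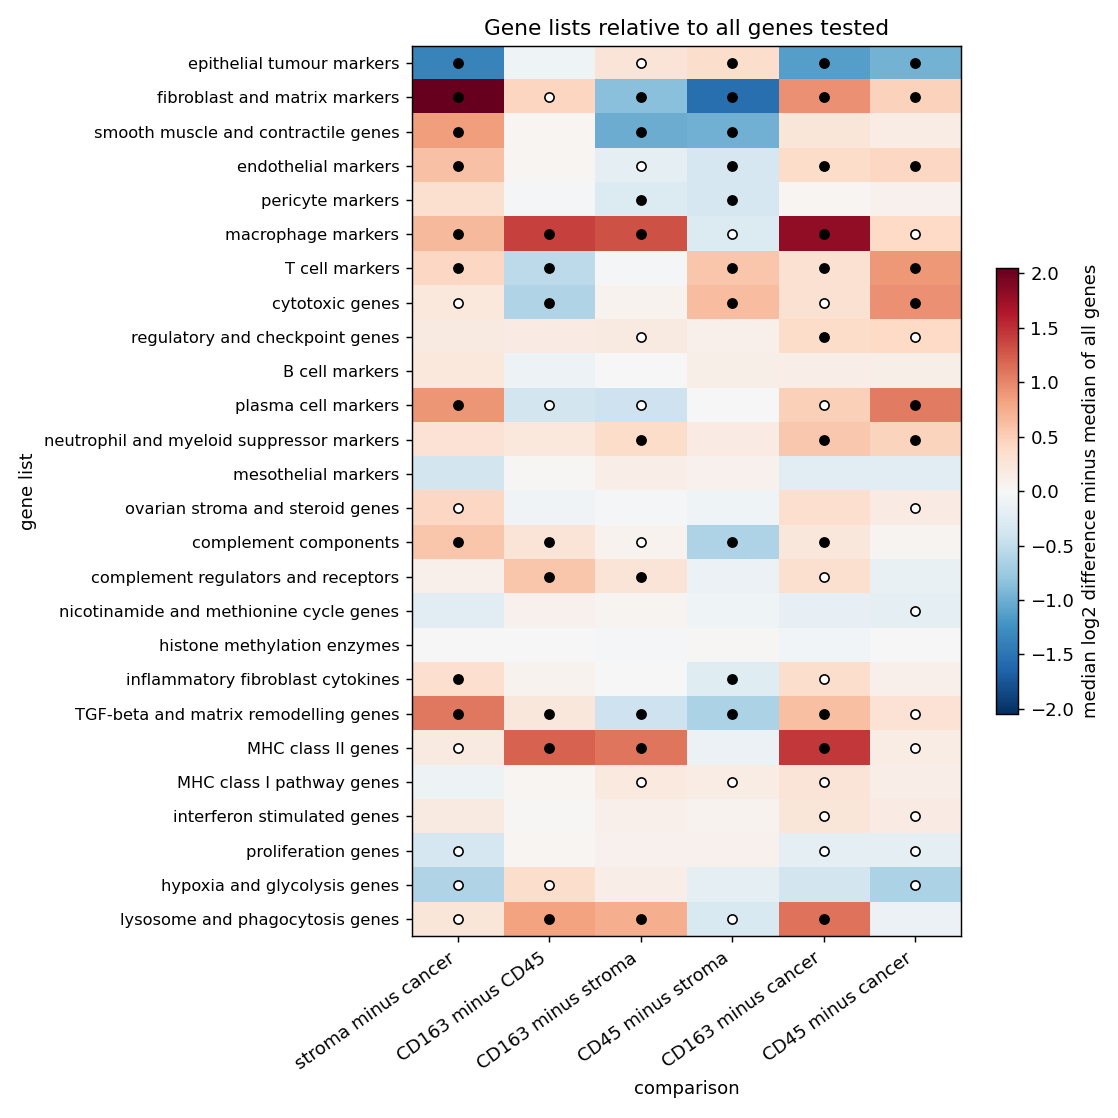
Each square is the median log2 difference of a list's genes minus the median of all genes tested, for 26 lists and 6 comparisons (red higher, blue lower in the first-named type). The epithelial list includes its 4 keratins. Filled dots are the 55 camera calls that hold with an estimated correlation and open dots the 34 that do not; fibroblast markers stand 2.04 above the median of all genes between stroma and cancer.

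Camera called 89 of the 156 lists and comparisons, 62 up and 27 down, and 55 of these hold with an estimated correlation. With third-quartile scaling 81 of the 89 were called in the same direction, without shallow areas 83, and 0 in the opposite direction in either. Third-quartile scaling moves all genes of an area nearly alike, and camera sets a list against the other genes. Agreement of the list calls under that scaling was therefore close to fixed in advance and lends them no support. Without the region block 77 were called in the same direction, 12 were not called, and 13 others were; of the 12, complement, pericyte and cytokine lists between CD45 areas and stroma hold with an estimated correlation. B cell markers, mesothelial markers and histone methylation enzymes had no call in any comparison (smallest adjusted p = 0.094, 0.203 and 0.55). Mast cell and adipocyte markers had too few genes tested (2 and 1).

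Genes higher in one area type than in each of the other 3 numbered 201 in stroma, 5025 in cancer, 147 in CD163 and 38 in CD45 areas. In stroma the smallest of the 3 differences was largest for COL1A1 (1.93), COL1A2 (1.85), AEBP1 (1.61), BGN (1.53), CCN1 (1.53) and COL6A2 (1.47). In cancer areas it was largest for WFDC2 (2.21), BCAM (2.13), MSLN (1.94), MUC1 (1.85), LAPTM4B (1.78) and SOX17 (1.77), leaving out keratins. In CD163 areas C1QB (2.11), C1QA (2.06), C1QC (1.84), IFI30 (1.77), LAPTM5 (1.71) and SPP1 (1.69) led, and in CD45 areas CD3E (0.96), CCL5 (0.94), TRAC (0.88), CD52 (0.83), TRBC1 (0.79) and IL2RB (0.70), the last of which, with CD52, was chosen after its value was seen. With third-quartile scaling the counts were 240, 919, 164 and 74, and 165, 919, 133 and 38 of the genes were shared with those above. Without shallow areas the counts were 127, 2076, 177 and 105, with 121, 2053, 127 and 37 shared. Regions share patients, so the p-values behind these limma calls are too small.

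Across the 38 regions with both stroma and cancer areas, NNMT in stroma rose with the matrix and cytokine scores of the same stroma area. It was related to the TGF-beta and matrix remodelling score at r = 0.781 (rho = 0.740) and to the fibroblast and matrix score at r = 0.746 (rho = 0.724), and to the inflammatory fibroblast cytokine score at r = 0.741 (rho = 0.714). Each had a permutation p of 1e-05, the smallest that 100000 resamples can give, and an adjusted p of 4.75e-05 (Benjamini-Hochberg over 19 relations). With the first principal component of each list as score these were 0.807, 0.763 and, for cytokines, 0.426 (adjusted p = 0.0101). Without the 2 regions farthest from the median NNMT the 3 mean scores stood at 0.737, 0.706 and 0.695, within plate 1 0.891, 0.790 and 0.774, and within plate 2 0.699, 0.776 and 0.713. Macrophage markers (r = 0.615, rho = 0.628, permutation p = 6e-05), MHC class II genes (0.570, 0.584, 2.2e-04), contractile genes (0.557, 0.523, 3.4e-04), interferon stimulated genes (0.514, 0.520, 6.6e-04), T cell markers (0.492, 0.424, 0.00164) and epithelial markers (0.480, 0.455, 0.00265) were related too. The largest adjusted p of these was 0.00387, and r ran from 0.447 to 0.591, and 0.6 for MHC class II genes, without the same regions. Without keratins the epithelial relation was 0.353 (rho = 0.339, adjusted p = 0.0358). Contractile and epithelial scores were not called within plate 1 (r = 0.463 and 0.426), where p-values rest on 20 regions. By rho the relation with T cell markers ended with quantile normalization (0.312) and within both plates (0.499 and 0.406), that with epithelial markers with third-quartile scaling (0.319), and those with MHC class II (0.510) and interferon stimulated genes (0.463) within plate 1. Random lists matched on size and level were related to NNMT as well, with a median r of 0.372 for the TGF-beta list. The TGF-beta, fibroblast and cytokine scores lay at percentile 100 of these, macrophage markers at 99.7 and T cell markers at 99.5. Contractile, MHC class II, interferon and epithelial scores lay between 91 and 94.5. The random lists were not matched on the correlation among members, so a high percentile cannot be read as a relation with NNMT particular to a list. The check was run for scores in stroma areas alone.

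The complement score without C1q genes was not related to NNMT in stroma (r = 0.199, rho = 0.167, permutation p = 0.232, adjusted p = 0.232). Its r was −0.039 within plate 1 and 0.148 without the 2 farthest regions, and it turned to −0.011 with quantile normalization. It was past the threshold within plate 2 (r = 0.538, adjusted p = 0.028) and over all 55 stroma areas (r = 0.269, adjusted p = 0.0497). Over the 38 regions it lay at percentile 9.79 of random lists. Its members went both ways, in a family of 13 genes tested after the data were seen. C3, the central component, was related at r = 0.597 (permutation p = 5e-05, Benjamini-Hochberg adjusted p = 3.9e-04), CFB at 0.510 (adjusted p = 0.0024) and C1S at 0.461 (0.00767). The C1q genes C1QA, C1QB and C1QC were related at 0.627, 0.575 and 0.578, and C7 at −0.536 (adjusted p = 0.00166). C1R, C2, C4B, C6 and CFD were not related past the threshold (r from −0.115 to 0.310).

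NNMT in stroma was also related to NNMT in the cancer area of the same region (r = 0.684, rho = 0.654, permutation p = 1e-05, adjusted p = 4.75e-05, n = 38). So it was to NNMT in the CD163 area (r = 0.606, rho = 0.561, p = 1.6e-04, adjusted p = 5.07e-04, n = 35), but not past the threshold in the CD45 area (r = 0.327, rho = 0.339, adjusted p = 0.102, n = 27). Within plates these were 0.740 and 0.624, 0.819 and 0.602, and 0.379 and 0.462; without the 2 farthest regions 0.640, 0.528 and 0.316. Proliferation genes of the cancer area (r = 0.529, rho = 0.514, p = 5.1e-04, adjusted p = 0.00108) and its interferon stimulated genes (0.521, 0.482, 6.6e-04, 0.00114) were related. Within plates r was 0.539 and 0.641, and 0.482 and 0.706, and without the 2 farthest regions 0.498 and 0.475. The call of proliferation ended with third-quartile scaling (0.283, adjusted p = 0.109) and with quantile normalization (0.265, adjusted p = 0.137). By rho the interferon relation ended with both scalings (0.229 and 0.317, adjusted p = 0.187 and 0.0775) and within plate 1 (0.403), and NNMT in CD163 areas ended within plate 2 (0.494, adjusted p = 0.068). In the same order of values, MHC class II genes (0.429, 0.417, 0.0107, 0.0135) and neutrophil markers (0.430, 0.357, 0.0107, 0.0135) of the CD163 area were related. They stood at 0.406 and 0.278 without the 2 farthest regions, where the neutrophil relation lost its call (adjusted p = 0.139) and stayed positive. By rho the neutrophil call also ended with a pseudocount of 5 (0.342) and with quantile normalization (0.296). It ended by rho within both plates (0.481 and 0.391) and given recovered negative-probe reads (0.265) too. Within plates r was 0.459 and 0.657 for MHC class II genes, and 0.505 and 0.487 for neutrophil markers. MHC class II genes missed the threshold in plate 1 (adjusted p = 0.0637) and neutrophil markers in plate 2 (adjusted p = 0.0675). The MHC class II relation also ended with quantile normalization (0.287, adjusted p = 0.128). Cytotoxic genes of the CD45 area were positively related (0.435, 0.452, 0.0235, 0.028), and the call ended without the 2 farthest regions (0.349, adjusted p = 0.11), with third-quartile scaling (0.327, adjusted p = 0.112) and with quantile normalization (0.275, adjusted p = 0.184); within plates r was 0.566 and 0.483, the latter not called (adjusted p = 0.12), and by rho the call ended in both plates (0.543 and 0.531, adjusted p = 0.0601 and 0.0944). T cell markers there missed the threshold (0.360, 0.359, 0.0656, 0.0734), at 0.486 and 0.482 within plates and 0.229 without the 2 farthest; they passed it over all stroma areas (0.351, adjusted p = 0.0497) and given recovered negative-probe reads (0.448, adjusted p = 0.0207). Mclust found 1 cluster of NNMT over regions. Regions share patients, so all these p-values are too small.

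**Figure D4:**
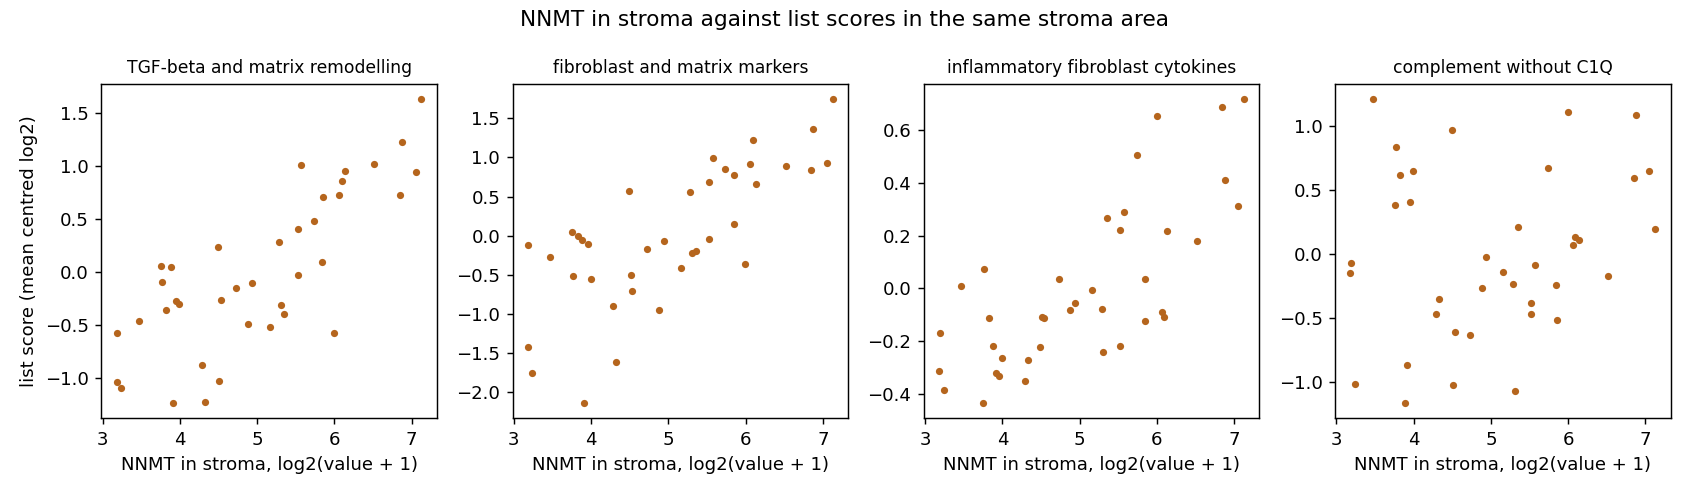
Each point is the stroma area of 1 of 38 regions; the x axis is NNMT on the log2(value + 1) scale and the y axis the mean centred log2 value of a list's genes. The TGF-beta (r = 0.781), fibroblast (0.746) and cytokine scores (0.741) rise with NNMT, and the complement score without C1q (0.199) was not related past the threshold.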

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

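Tests with third-quartile scaling, without shallow areas, both together, edgeR without shallow areas and the covariate of recovered negative-probe reads were chosen after the data were seen. NNMT was higher in stroma than in CD163 and CD45 areas in every alternative run, and past the threshold in each except CD163 within plate 1; its excess over cancer areas kept its direction in every alternative run and missed the threshold only without the region block. Of the 218 values of genes named in the comparisons, 210 kept their direction and their side of the threshold with third-quartile scaling, 203 without shallow areas and 201 without the block, against 171 within plate 2. With a pseudocount of 5 this held for 217, and without a filter for 217. Of the 89 camera calls, 55 hold with an estimated correlation, and without the block 77 kept their direction and call. The planned covariate of the negative-probe value, and the relations given it, were not run because that value is the same in every area. Depth limits the CD45 areas most: without shallow areas 15 of 33 regions remained for CD45 against stroma, and 13 of 33 for CD163 against CD45. Counts that moved by over 1.5 times, or whose larger direction turned, calls of NNMT that ended, gene values that turned and relations that gained or lost a call are given below; apart from fewer genes or areas the cause was not tested.

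Without the region as a replicate block limma called 446 genes for CD163 against CD45 (398 higher, 48 lower), 1488 for CD163 against stroma (225, 1263) and 3017 for CD45 against stroma (91, 2926). The call of NNMT ended, at 0.43 for stroma against cancer, −0.21 for CD163 against cancer and −0.40 for CD45 against cancer. With region as a random block limma called 1805 genes for CD163 against stroma (289 higher, 1516 lower) and 3437 for CD45 against stroma (112, 3325). NNMT lost its call, at −0.25 for CD163 against cancer. With the filter at 50% of areas, which tests fewer genes, limma called 1641 genes for stroma against cancer (106 higher, 1535 lower), 396 for CD163 against CD45 (387, 9), 389 for CD163 against stroma (85, 304), 906 for CD45 against stroma (14, 892), 1867 for CD163 against cancer (91, 1776) and 2004 for CD45 against cancer (25, 1979). Type by type, genes higher there than elsewhere numbered 70 in stroma, 1472 in cancer, 39 in CD163 and 1 in CD45.

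With quantile normalization limma called 3424 genes for stroma against cancer (1115 higher, 2309 lower), 2100 for CD163 against stroma (383, 1717), 2628 for CD45 against stroma (290, 2338), 4370 for CD163 against cancer (738, 3632) and 4200 for CD45 against cancer (464, 3736). Genes higher in one type than in the other 3 numbered 507 in stroma, 1652 in cancer and 60 in CD45. The call of NNMT ended, at −0.11 for CD163 against cancer and −0.29 for CD45 against cancer. C3 turned to 0.05 for stroma against cancer. With the negative probe subtracted limma called 2617 genes for stroma against cancer (1149 higher, 1468 lower), 1024 for CD163 against stroma (544, 480), 1460 for CD45 against stroma (798, 662), 2717 for CD163 against cancer (1380, 1337) and 2562 for CD45 against cancer (1396, 1166). The genes higher in one type than in each other numbered 627 in cancer and 91 in CD45. NNMT lost its call, at −0.07 for CD45 against cancer. NNMT turned to 0.08 for CD163 against cancer and C3 turned to 0.03 for CD163 against cancer. In the regions with all 4 area types, which are fewer, limma called 564 genes for CD163 against stroma (175 higher, 389 lower).

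Within plate 1 limma called 678 genes for CD163 against stroma (447 higher, 231 lower), 820 for CD45 against stroma (132, 688) and 4567 for CD163 against cancer (463, 4104). Genes higher in one type than in the other 3 numbered 129 in stroma and 2931 in cancer. The call of NNMT ended, at −0.49 for CD163 against stroma, −0.07 for CD163 against cancer and −0.36 for CD45 against cancer. Stroma with against without a cancer area gave 356 calls (14 higher, 342 lower). Within plate 2 limma called 3576 genes for stroma against cancer (162 higher, 3414 lower), 93 for CD163 against CD45 (83, 10) and 658 for CD45 against stroma (11, 647). The genes higher in one type than in each other numbered 102 in stroma, 2928 in cancer, 25 in CD163 and 3 in CD45. WFDC2 turned to −0.15 for CD45 against stroma and GZMA turned to 0.09 for CD163 against CD45. Stroma with against without a cancer area gave 0 calls (0 higher, 0 lower), with 806 at an unadjusted p under 0.05 by limma. By edgeR with TMM the calls were 5301 genes for stroma against cancer (2854 higher, 2447 lower), 1675 for CD163 against stroma (978, 697), 1350 for CD45 against stroma (828, 522), 4275 for CD163 against cancer (2350, 1925) and 3262 for CD45 against cancer (1972, 1290). Type by type, genes higher there than elsewhere numbered 1004 in cancer, 282 in CD163 and 208 in CD45. Calls of NNMT were lost, at 0.00 for CD163 against cancer and −0.14 for CD45 against cancer. C6 turned to 0.09 for stroma against cancer.

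By edgeR with RLE the calls were 938 genes for CD163 against CD45 (413 higher, 525 lower), 1648 for CD163 against stroma (980, 668), 1439 for CD45 against stroma (977, 462), 4198 for CD163 against cancer (1898, 2300) and 3131 for CD45 against cancer (1736, 1395). Genes higher in one type than in the other 3 numbered 1124 in cancer, 264 in CD163 and 233 in CD45. The call of NNMT ended, at −0.05 for CD163 against cancer and −0.16 for CD45 against cancer. C6 turned to 0.04 for stroma against cancer. With third-quartile scaling limma called 2674 genes for stroma against cancer (1268 higher, 1406 lower), 968 for CD45 against stroma (221, 747), 2678 for CD163 against cancer (981, 1697) and 2409 for CD45 against cancer (886, 1523). The genes higher in one type than in each other numbered 919 in cancer and 74 in CD45. NNMT lost its call, at −0.01 for CD163 against cancer and −0.18 for CD45 against cancer. C6 turned to 0.06 for stroma against cancer. Stroma with against without a cancer area gave 444 calls (102 higher, 342 lower). Without shallow areas limma called 749 genes for CD163 against CD45 (288 higher, 461 lower), 1052 for CD163 against stroma (691, 361), 1111 for CD45 against stroma (850, 261) and 2753 for CD45 against cancer (302, 2451). Type by type, genes higher there than elsewhere numbered 127 in stroma, 2076 in cancer and 105 in CD45. Calls of NNMT were lost, at −0.12 for CD163 against cancer and −0.20 for CD45 against cancer.

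Without shallow areas and with third-quartile scaling limma called 3158 genes for stroma against cancer (1496 higher, 1662 lower), 2229 for CD163 against stroma (335, 1894), 3666 for CD163 against cancer (707, 2959) and 2472 for CD45 against cancer (321, 2151). Genes higher in one type than in the other 3 numbered 423 in stroma, 1102 in cancer and 67 in CD45. The call of NNMT ended, at −0.17 for CD45 against cancer. NNMT turned to 0.02 for CD163 against cancer and C6 turned to 0.08 for stroma against cancer. By edgeR with TMM and without shallow areas the calls were 1266 genes for CD163 against stroma (732 higher, 534 lower), 848 for CD45 against stroma (462, 386), 3443 for CD163 against cancer (1549, 1894) and 1745 for CD45 against cancer (777, 968). The genes higher in one type than in each other numbered 761 in cancer, 228 in CD163 and 116 in CD45. NNMT lost its call, at 0.00 for CD163 against cancer and −0.07 for CD45 against cancer. C6 turned to 0.08 for stroma against cancer and C1S turned to 0.07 for CD45 against cancer. With recovered negative-probe reads as a covariate limma called 578 genes for CD163 against stroma (363 higher, 215 lower), 303 for CD45 against stroma (103, 200), 1834 for CD163 against cancer (267, 1567) and 1195 for CD45 against cancer (83, 1112). Type by type, genes higher there than elsewhere numbered 114 in stroma and 823 in cancer. Calls of NNMT were lost, at −0.16 for CD163 against cancer and −0.39 for CD45 against cancer. C3 turned to 0.17 for CD163 against cancer. Stroma with against without a cancer area gave 226 calls (6 higher, 220 lower).

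Without a filter genes higher in one type than in the other 3 numbered 61 in CD45.

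The comparison of stroma in regions with all 4 types (27) against regions with stroma alone (10) gave 3851 calls (216 higher, 3635 lower), against 864 for stroma with against without a cancer area. NNMT was higher in regions with all 4 types at 1.62 and called, against 0.61 without a call. Regions with stroma alone lack CD163 and CD45 areas too, so a cancer area cannot be told apart from immune areas in this comparison.

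Relations of NNMT in stroma lost their call as follows. With quantile normalization these were proliferation genes in cancer (r = 0.265), MHC class II genes in CD163 (0.287) and cytotoxic genes in CD45 areas (0.275). Within plate 1 they were contractile (0.463) and epithelial scores in stroma (0.426) and MHC class II genes in CD163 areas (0.459), and within plate 2 cytotoxic genes in CD45 (0.483) and neutrophil markers in CD163 areas (0.487). Without the 2 regions farthest from the median NNMT cytotoxic genes (0.349) and neutrophil markers (0.278) lost it, and with third-quartile scaling proliferation (0.283) and cytotoxic genes (0.327). The complement score gained a call within plate 2 (0.538) and over all stroma areas (0.269), and T cell markers in CD45 areas over all stroma areas (0.351) and given recovered negative-probe reads (0.448). By rho 16 of the 19 relations were called, 15 with a pseudocount of 5, 10 with quantile normalization, 7 and 13 within plates, 14 without the 2 farthest regions, 17 over all stroma areas, 13 with third-quartile scaling and 16 given recovered negative-probe reads. With the first principal component as score the cytokine relation kept its call at 0.426, against 0.741.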

Other observations

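The comparison of stroma with and without a cancer area in the region, the area-type comparisons and the stroma signal in CD163 areas were planned or predicted before their results were seen; third-quartile scaling, the test without shallow areas, the tests with recovered negative-probe reads or at equal reads and the single-gene values below were chosen after the results were seen. Stroma areas of the 38 regions that also held a cancer area differed from those of the 17 regions without one, in genes chosen after their values were seen. The collagens COL1A1 (2.47 ± 0.47), COL1A2 (1.74 ± 0.40) and COL3A1 (1.64 ± 0.40), the proteoglycan BGN (1.63 ± 0.32), fibronectin FN1 (1.38 ± 0.45) and SPARC (1.14 ± 0.33) were higher where a cancer area was present, and so were HLA-B (1.21 ± 0.32), CD74 (1.20 ± 0.34) and SPP1 (1.16 ± 0.31), with limma (Benjamini-Hochberg, largest adjusted p = 0.0404). The nuclear receptors NR4A1 (−1.75 ± 0.33), NR4A2 (−1.35 ± 0.27) and NR4A3 (−1.10 ± 0.21), the metalloprotease ADAMTS1 (−1.45 ± 0.28), the hormone-response gene GREB1 (−1.35 ± 0.25), the steroid transport gene STAR (−1.24 ± 0.24), CCN5 (−1.23 ± 0.22), JUND (−1.19 ± 0.22) and KLF2 (−1.02 ± 0.23) were lower. Of the lists, fibroblast and matrix markers had 9 higher and 1 lower of 21 (13 called when adjusted over the list alone), MHC class II genes 2 and 0 of 10 (7), and ovarian stroma and steroid genes 0 and 5 of 7 (6). Fibroblast and MHC class II lists were called up by camera and hold (adjusted p = 0.0329 and 0.0247 with an estimated correlation), and so were TGF-beta, endothelial, pericyte, MHC class I and interferon lists (0.0354, 0.0337, 0.0247, 0.0337 and 0.0247). Epithelial tumour markers without keratins were called up and hold too (adjusted p = 1.33e-08, and 0.0242 with an estimated correlation), with 0 of 16 members called (2 higher when adjusted over the list alone) and a median 0.289 above that of all genes, and BCAM, a gene higher in cancer areas, was higher by 0.64 ± 0.17, so cancer-cell signal in the stroma areas of regions with a cancer area stays open. The steroid list was called down and lost (adjusted p = 0.0514 with an estimated correlation), as were the macrophage, plasma cell, complement, lysosome, cytokine, proliferation and hypoxia lists, called up.

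Limma called 864 genes there, 41 higher and 823 lower, with a median of all genes of −0.16, and NNMT differed by 0.61 ± 0.31 without passing the threshold (adjusted p = 0.177). With the 27 regions that held all 4 types set against the 10 with stroma alone, as planned, NNMT was higher in the 27 by 1.62 ± 0.33 and was called (limma, adjusted p = 1.58e-04), beside 3851 genes. The 10 lack CD163 and CD45 areas as well, so a cancer area cannot be told apart from immune areas there. In the other alternatives run NNMT was not called (0.45 to 0.73, limma, smallest adjusted p = 0.134). Against the median of all genes of −0.16 the median fibroblast marker stood at 0.79 and the median steroid gene at −0.46. The split was 102 to 342 with third-quartile scaling, 171 to 407 with quantile normalization and 6 to 220 with recovered negative-probe reads as a covariate. Within plate 1 (20 against 9 areas) 356 genes were called, and within plate 2 (18 against 8) 0, with 806 at an unadjusted p under 0.05 by limma. Of the genes called over both plates, 100% kept their direction within plate 2, whose areas were part of that call. The labels do not give the tissue site of a region, so what parts these regions is unknown. Regions share patients, so these p-values are too small.

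Most of the genes called between stroma and cancer areas were lower in stroma, 94.1%. Deeper cancer libraries as the whole account are argued against only where depth acts along a straight line. With recovered negative-probe reads as a covariate the median of all genes was −0.25 (bootstrap SE 0.035), against −0.302 without it. With it 92.4% of the calls were lower in stroma. That covariate is also the amount each area was scaled by. The same covariate took the calls between CD45 and cancer areas from 7430 to 1195. At equal total reads, by a line over regions, the median was −0.255 (SE 0.039). That point lies near the edge of the data, since the cancer area had more reads in 34 of the 38 regions. Depth as a part of it stays open. The mean of the regional medians was −0.123 (SE 0.133) in the 4 regions whose stroma area had at least as many reads. It was −0.313 (SE 0.03) in the other 34. The first value lies within its SE of 0, so it does not speak against depth as the whole account either, and 4 regions are too few. The scaling to the negative probes stays open as well. With third-quartile scaling the share was 52.6%, but that scaling centres the areas on each other (median of all genes 0.021), which fixes a near-even split under either account. That cancer cells hold more RNA of most genes was not tested.

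More genes were lower than higher in CD45 areas against stroma, 93.4% of the calls. Without shallow areas 23.5% were lower, but with third-quartile scaling the share was 77.2% in all areas and 90.4% without the shallow ones (165 higher, 1558 lower), and by edgeR with TMM 38.7% and 45.5%. What leaving out shallow areas does to the share thus differs with the scaling, and whether the lower calls come from areas where most genes lie at 1 read cannot be told apart from the scaling. Leaving those areas out also left 15 of the 33 regions with both areas, and no biological explanation was tested.

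NNMT lay above the negative probes in cancer and CD163 areas too, which could be stroma signal taken up there. After the negative probe was subtracted, NNMT in CD163 areas was 42.6% of its stroma level (95% bootstrap interval 33 to 53.2), among the 21 fibroblast markers with a median of 39.3% and a highest of 66.2% (FN1), consistent with stroma signal. In cancer areas NNMT was at 65.7% (47.8 to 85.8), above all 21 markers, which had a median of 14.9% and a highest of 51.9% (FAP). The interval reaches below that highest marker, so stroma signal and NNMT made in cancer cells cannot be told apart. NNMT made by cancer cells or macrophages stays open as an untested biological explanation.

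Random labelling of areas within regions can be excluded as the source of the counts of calls between area types. The areas were sorted by stain and differed in depth by type. The splits therefore cannot tell differences in RNA from calls that come with depth. With area types permuted within regions, 1 of 100 splits, the real one, gave as many genes in each comparison: 6033 between stroma and cancer (highest other 422), 731 between CD163 and CD45 (23), 958 between CD163 and stroma (17), 1716 between CD45 and stroma (26), 7106 between CD163 and cancer (296) and 7430 between CD45 and cancer (909). The genes higher in one area type than in the other 3 numbered 201, 5025, 147 and 38 for stroma, cancer, CD163 and CD45, against 0 in the highest other split of each. For stroma with against without a cancer area 1 of 100 splits gave as many as 864 genes, and the highest other gave 2. That would exclude chance only if areas varied independently, so it is not excluded for regions that share patients. The splits of stroma areas, unlike those within regions, exchange regions as if independent. As 65 regions come from 30 patients, the spread of the other splits is too narrow. Within plate 2, with 18 against 8 areas, limma called 0 genes.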
